A study of Sus scrofa with 4 samples.

How the data were processed

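Small RNA libraries of pig longissimus dorsi, the long muscle of the back, were sequenced on a HiSeq 2000, per the labels. There were 4 libraries, 1 for each of 4 breeds. RNA was extracted with Trizol and libraries were made from total RNA with a Balancer kit for small RNA, per the labels' protocols. Diannan Small Ear and Tibetan pigs formed the indigenous type, and Landrace and Yorkshire pigs the introduced type, with 2 libraries each. The labels do not say whether a library held the RNA of one animal or a pool, and they give no batch, age or sex. The p-values therefore measure only the spread between these libraries, part of which may be technical.

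The deposited table lists 271 known miRNAs with whole-number read counts per library, per the file headers. The aligner, the miRNA database and the genome build are not given in the sources used here, so no coordinates are printed. The authors also deposited CPM values, counts scaled to the total of the library, which equalled each count over the total of its column to within 4.2e-05. A further pair of deposited columns holds a mean signal per type, made by the authors from the CPM values. All 542 of these means (within 0.0001 CPM) followed 1 rule, and 505 of them also equalled the plain mean of both libraries. A library was left out of the mean of a miRNA that was at 0 in that library and in its partner, where Diannan Small Ear is the partner of Landrace and Tibetan of Yorkshire, and a mean with nothing left was set to 1e-05. The authors' fold column is the ratio of these means, per the file headers, and reaches 122446 where a mean sits at that floor. The authors deposited p-values and FDR values as well, and the test behind them is not given in the sources used here.

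All tests here started from the counts as deposited. Names were unique, so no rows were merged. Rows with at least 10 reads were compared and no 2 of them held identical counts. Near-identical mature sequences, such as the let-7 family, miR-10a and miR-10b, miR-29b and miR-29c, miR-199a-3p and miR-199b-3p, or the rows miR-196b and miR-196b-5p, may share reads, and their separate values are uncertain.

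The types were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) after filterByExpr, which kept 197 miRNAs, and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 2 libraries against 2 there were 2 residual degrees of freedom. Fold changes are log2 values of indigenous over introduced, with their standard error (SE). Breeds were compared within a type with no test, since each had 1 library. Ratios of TMM-scaled counts carry a 95% exact binomial interval and shares a 95% Wilson interval. These intervals and the Fisher's exact tests on reads cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 counts, which was 0.561 to 1.20 CPM over the 4 libraries.

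Lists of miRNAs were fixed before the data were examined, 16 in all. They covered striated muscle miRNAs, miRNAs inside slow-fibre myosin genes, adipocyte differentiation and lipid metabolism, muscle growth, regeneration and atrophy, the let-7 and miR-30 families, the miR-17-92 and paralogous clusters, the imprinted DLK1-DIO3 cluster, HOX-cluster miRNAs, and markers of erythroid cells, white blood cells, endothelium, stroma, liver, epithelium and neural tissue. The 14 lists with at least 3 tested members were tested with camera (limma 3.58.1, two-sided) on log2 CPM at a preset correlation of 0.01, adjusted over the lists. A list's median is the median over its members of the difference in mean log2 CPM (prior count 2) between types.

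The miRNAs named in the text followed a rule set before the data were examined. In the comparison of types they were those past the threshold with types that did not overlap, or, where fewer than 5 in a direction passed, those with the smallest p among miRNAs with a mean of at least 10 CPM. In each list they were the 3 most abundant members, within a type the 5 largest ratios in each direction (at least 100 counts in 1 library and 10 in the other), and for composition the 10 largest mean shares. The rule for ratios was used as well for the pairs of libraries that cross the types. miR-122, miR-196b-5p and miR-29a, the set with opposite directions in the 2 library pairs, and the precursors named for their arms, were chosen after their values were seen.

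Alternatives planned before the data were examined were RLE, upper-quartile and total-count scaling, no low-count filter and a stricter one (50 counts in 2 libraries), DESeq2 1.42.0, limma-voom, a robust fit, the table without its 5 most abundant miRNAs, and each library left out in turn. After the data were seen, a term for the library pair (Diannan Small Ear with Landrace, Tibetan with Yorkshire) was added to the model, and the 2 types were compared within each pair. A fit with 1 library left out sets 1 library against 2, unbalanced over the library pairs, so pair differences enter it. On simulated data with 197 miRNAs per run, of which 40 were changed, over 20 runs, the test of type alone recovered 0% of 16-fold changes. With the pair term it recovered 80.0% of 16-fold, 47.7% of 4-fold and 13.9% of 2-fold changes and called 0.669% of unchanged miRNAs. The simulated counts took their means and spread from a fit of the library pair to these same libraries, so the pair term was correct by construction. The 0.669% is therefore not the rate of false calls in the real data. In a separate simulation camera called the striated muscle list, raised 4-fold, in 20 of 20 runs without the pair term. The simulated miRNAs varied independently, so this does not show how camera behaves where list members move together. R 4.3.3 and Python 3.11.15 were used.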

Results

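The miRNAs of longissimus dorsi muscle were profiled in 4 pig breeds, with 1 small RNA library per breed. Diannan Small Ear and Tibetan pigs are indigenous Chinese breeds, and Landrace and Yorkshire are introduced breeds. The series addresses growth and lipid deposition in muscle. Reads counted to the 271 listed miRNAs totalled 4500803 for Diannan Small Ear, 3592704 for Tibetan, 2507082 for Landrace and 5346460 for Yorkshire. Of these miRNAs, 249, 246, 253 and 232 had at least 1 read, in the same order.

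The miRNA pool of each library was dominated by a single miRNA, and that miRNA differed between the breeds of a type. miR-1, a muscle-specific miRNA that promotes myoblast differentiation, made up 83.4% of the Tibetan counts (95% Wilson interval 83.4 to 83.4) and 92.6% of the Yorkshire counts (92.6 to 92.7). It held 0.256% (0.252 to 0.261) in Diannan Small Ear and 0.355% (0.348 to 0.363) in Landrace. miR-10b, encoded in a HOX gene cluster, made up 61.9% (61.8 to 61.9) of the Diannan Small Ear and 46.0% (45.9 to 46.0) of the Landrace counts, and 0.526% (0.518 to 0.533) and 0.177% (0.173 to 0.181) in Tibetan and Yorkshire. miR-486, abundant in muscle and red blood cells, held 11.8% (11.8 to 11.8) in Diannan Small Ear and 14.2% (14.2 to 14.3) in Landrace, against 0.572% (0.565 to 0.580) in Tibetan and 0.200% (0.196 to 0.203) in Yorkshire.

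Over the 4 libraries the mean shares of the most abundant miRNAs were 44.2% for miR-1, 27.1% for miR-10b, 6.70% for miR-486, 4.02% for miR-133a-3p, 1.90% for miR-26a, 1.71% for miR-22-3p, 1.61% for miR-206, 1.54% for miR-191, 1.5% for miR-143-3p and 1.16% for miR-10a-5p. The 10 most abundant miRNAs of a library took between 87.5% (Landrace) and 98.3% (Yorkshire) of its counts.

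**Figure D1:**
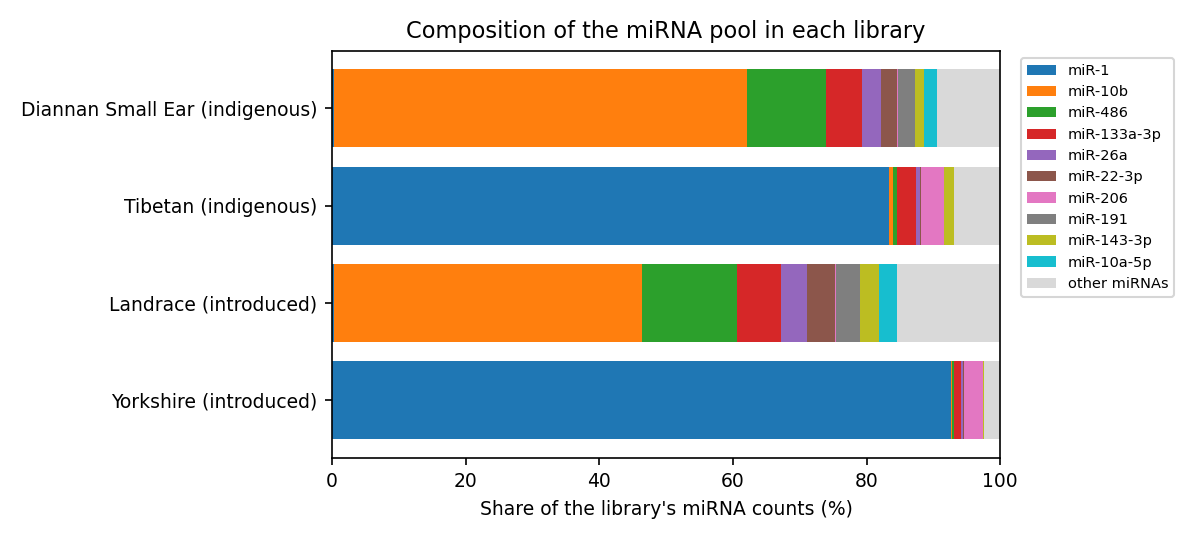
Share of each library's miRNA counts (percent, horizontal axis) taken by the 10 miRNAs with the highest mean share, in 1 bar per library. miR-10b leads in Diannan Small Ear (61.9%) and Landrace (46.0%), and miR-1 in Tibetan (83.4%) and Yorkshire (92.6%).

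The Diannan Small Ear and Tibetan libraries differed at least 2-fold in 124 of the 194 miRNAs with reads in both. Among the most different, miR-10b was 87.0-fold higher in Diannan Small Ear (95% counting interval 85.7 to 88.2), the liver-enriched miR-192 70.6-fold (47.7 to 109), miR-10a-5p 44.5-fold (42.0 to 47.3), miR-191 38.8-fold (37.0 to 40.7) and miR-204 27.2-fold (19.5 to 39.2). In the other direction, miR-1 was 440-fold lower in Diannan Small Ear (432 to 448), miR-374a-5p 140-fold (121 to 161), miR-3613 81.0-fold (47.0 to 153), the skeletal muscle miRNA miR-206 78.7-fold (75.7 to 81.8) and miR-152 46.2-fold (38.8 to 55.5). With 1 library per breed these differences have no replicate check, here and in the other comparisons of single breeds. Of the 124, 53 were higher and 71 lower in Diannan Small Ear, and with total-count scaling 136 differed, 73 higher and 63 lower.

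Landrace and Yorkshire, the introduced breeds, differed at least 2-fold in 128 of 192 miRNAs. miR-127, from the imprinted DLK1-DIO3 region, was 75.6-fold higher in Landrace (55.5 to 106), miR-192 59.1-fold (34.5 to 111), miR-10b 40.5-fold (39.7 to 41.3), miR-10a-5p 33.7-fold (31.2 to 36.5) and miR-191 33.5-fold (31.3 to 35.8). miR-1 was 1674-fold lower in Landrace (1640 to 1710), miR-206 147-fold (142 to 153), miR-374a-5p 107-fold (92.5 to 124), miR-152 22.3-fold (18.8 to 26.6) and miR-99a 20.2-fold (19.2 to 21.3). Of the 10 miRNAs named here, 8 were also named for Diannan Small Ear against Tibetan, in the matching direction. The 128 divided into 62 higher and 66 lower in Landrace, but with total-count scaling 155 differed, 141 higher and 14 lower, and the median log2 ratio of all miRNAs moved from -0.21 to 2.47. Total counts make every ratio of Landrace over Yorkshire 6.42 times larger, which leaves miR-1 261-fold, miR-152 3.47-fold and miR-99a 3.15-fold lower in Landrace.

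The libraries resembled each other across the types more than within them. Across 197 miRNAs, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.983 between Diannan Small Ear and Landrace and 0.973 between Tibetan and Yorkshire. It was 0.777 between the 2 indigenous and 0.774 between the 2 introduced libraries, and 0.771 and 0.783 in the remaining comparisons. The difference of Diannan Small Ear from Tibetan correlated with that of Landrace from Yorkshire (r = 0.896, Spearman's rho = 0.874). Diannan Small Ear with Landrace and Tibetan with Yorkshire are called library pairs here, and values within each pair stand beside the comparison of types. Each of the 4 libraries correlated most with a library of the other type, so the values cannot rule out labels exchanged between the types, which would alter every comparison of types. With TMM scaling 17 of 196 miRNAs differed at least 2-fold between Diannan Small Ear and Landrace, and 47 of 192 between Tibetan and Yorkshire. With total counts these were 64 and 155, the latter as many as between Landrace and Yorkshire, so the low counts depend on the scaling. Total counts multiply every ratio of Diannan Small Ear over Landrace by 0.602 and every ratio of Tibetan over Yorkshire by 2.86. Most of the differences then lay in 1 direction, 60 of 64 lower in Diannan Small Ear and 153 of 155 higher in Tibetan.

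**Figure D2:**
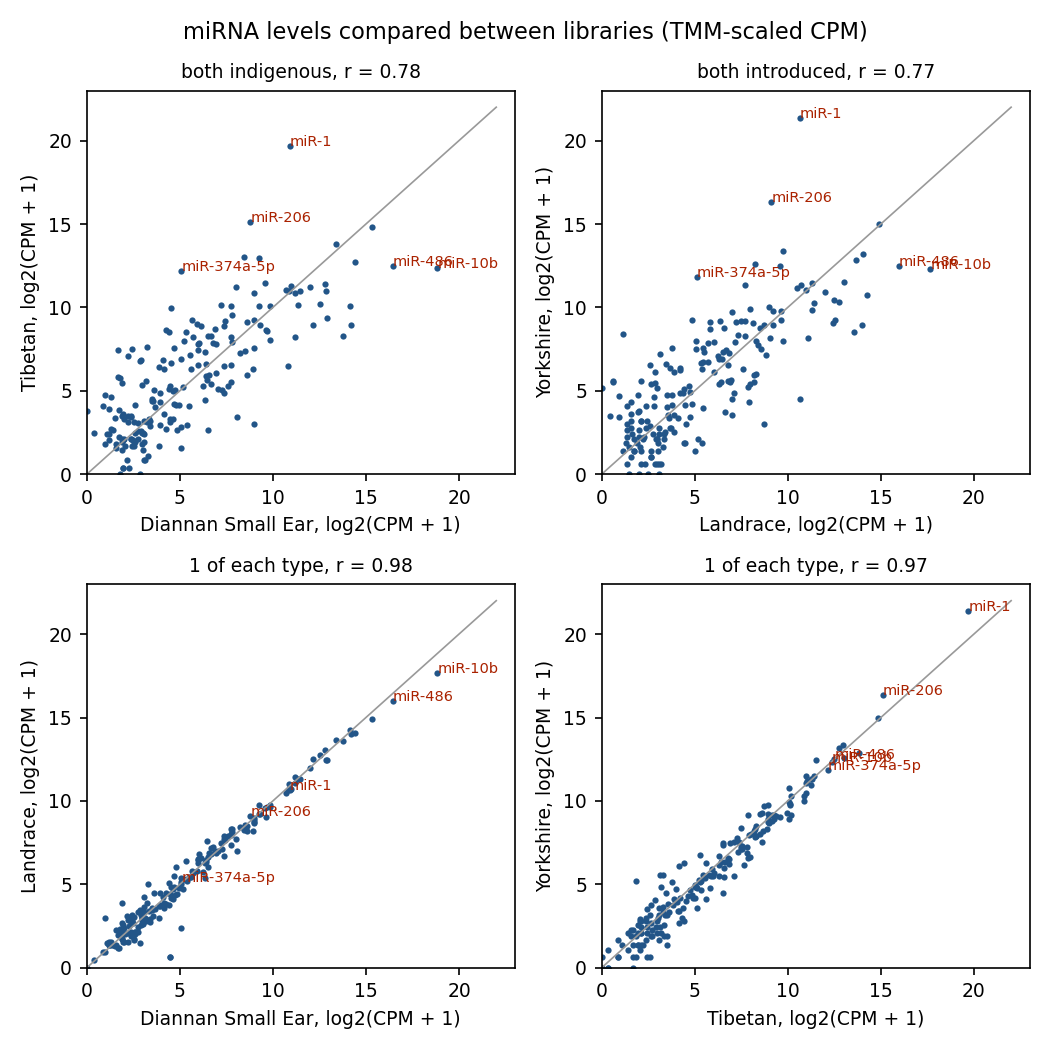
TMM-scaled levels of the 197 tested miRNAs, as log2(CPM + 1) on both axes, in libraries of the same type (upper panels) and in the library pairs (lower panels), with the line of equal levels. Points lie close to the line between Diannan Small Ear and Landrace (r = 0.983) and between Tibetan and Yorkshire (r = 0.973), and scatter widely within types (r = 0.777 and 0.774).

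Between the types, miR-29b, a repressor of collagen transcripts, had the smallest p of the 197 miRNAs. It measured 1.77 ± 1.09 CPM in indigenous and 21.1 ± 20.1 CPM in introduced breeds (TMM-scaled, SD, n = 2 each), a log2 fold change of -3.56 ± 1.31 (SE), and did not pass (edgeR adjusted p = 0.996). Its family member miR-29c (21.7 ± 6.76 against 66.6 ± 3.37 CPM, log2 fold change -1.61 ± 0.93) and miR-874 (7.85 ± 0.489 against 23 ± 7.47 CPM, -1.54 ± 0.89) had the next smallest p among lower estimates with at least 10 CPM. miR-208b, encoded in a slow myosin gene, had -1.01 ± 0.99 and miR-92b-3p -1.73 ± 1.73. Among higher estimates with at least 10 CPM, those with the smallest p were miR-363 (1.19 ± 0.88), miR-369 of the DLK1-DIO3 region (1.33 ± 1.29), miR-145-5p, typical of smooth muscle (1.05 ± 1.28), miR-99b (0.66 ± 0.85) and miR-196a of the HOX clusters (0.99 ± 1.30).

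In all, 0 of 197 miRNAs passed the threshold between the types by edgeR, by DESeq2 or by limma-voom, and 1 had an unadjusted p under 0.05 by each tool. The biological coefficient of variation was 98.6%, and the simulated test recovered 0% of 16-fold changes at this spread. With a term for the library pair, chosen after seeing the data, the coefficient was 35.3% and 1 miRNA passed. This was miR-29b, which was lower in the indigenous breeds (log2 fold change -3.29 ± 0.64, edgeR adjusted p = 0.000107). That fit had 1 residual degree of freedom and infinite prior degrees of freedom, so it used a spread shared over all miRNAs. Its SE and p therefore do not measure the spread of miR-29b itself. DESeq2 with the pair term called 0 (adjusted p = 0.211 for miR-29b). Under total-count scaling and without a low-count filter, edgeR with the pair term called 0 as well. The log2 fold change of miR-29b where the call was lost was -3.44 ± 1.06 with DESeq2, -2.86 ± 2.35 with total counts and -3.28 ± 0.46 without the filter.

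Within the library pairs miR-29b counts were 6 in Diannan Small Ear against 38 in Landrace, 6.85-fold lower (95% counting interval 2.87 to 19.8), and 9 in Tibetan against 65 in Yorkshire, 13.9-fold lower (6.88 to 31.7). miR-29c was 2.42-fold lower in the first pair (2.0 to 2.94) and 4.07-fold lower in the second (2.97 to 5.62), and miR-874 2.35-fold (1.64 to 3.43) and 3.44-fold (2.15 to 5.63). These 3 were the miRNAs at least 2-fold lower in the indigenous library of both pairs, and 0 were higher in both. By log2 CPM with a prior count of 2, where 15 and 44 miRNAs differed at least 2-fold, 1.66 in the same direction would be found if the pairs were independent. With total counts miR-29b was 11.4-fold and 4.85-fold lower, miR-29c 4.02-fold and 1.42-fold, and miR-874 3.91-fold and 1.20-fold, so that miR-29b alone was at least 2-fold lower in both pairs. The signs matched in 105 of 197 miRNAs, and r between the differences of the 2 pairs was -0.0688 (rho = 0.0645).

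Types that did not overlap, with both indigenous libraries above or both below the introduced ones, were found for 27 of 197 miRNAs (13.7%), 16 higher and 11 lower in indigenous breeds. Chance gives 33.3% for exchangeable libraries, which these were not, since pairs that cross the types make such separation rare. RLE scaling gave 10 higher and 15 lower, and total counts 4 in all. In miR-29b, miR-29c and miR-874 all 4 ratios between types were also at least 2-fold, and with total counts this held for miR-29b alone.

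Striated muscle miRNAs, which include miR-1, miR-133a-3p and miR-486, took 17.6% of the counts in Diannan Small Ear, 90.4% in Tibetan, 21.6% in Landrace and 96.9% in Yorkshire. Of the 9 tested members 0 passed, 0 also when adjusted over the list alone, and the same 0 holds for every other list in the test of type alone. With the pair term, 5 miRNAs in 4 lists passed when adjusted over the list alone. These were miR-499-5p (slow-fibre, log2 fold change -0.86 ± 0.35, edgeR adjusted p = 0.0431), miR-29b and miR-29c (muscle growth, miR-29c -1.64 ± 0.53, 0.0380), miR-127 (DLK1-DIO3, 1.01 ± 0.35, 0.0408) and miR-122 (liver, -1.68 ± 0.60, 0.0212). Over all tested miRNAs only miR-29b passed, and the edgeR adjusted p was 0.466 for miR-499-5p, 0.214 for miR-29c and 0.261 for miR-127 and miR-122. As for miR-29b, the SE and p of these 5 miRNAs use the spread shared over all miRNAs and do not measure their own. The log2 difference of miR-127 was 0.12 in the first pair and 2.03 in the second. Among the striated muscle miRNAs, the test of type alone gave log2 fold changes of -1.66 ± 4.15 for miR-1 and 0.43 ± 2.09 for miR-486. That of miR-133a-3p, a muscle miRNA linked to myoblast proliferation, was 0.15 ± 1.33. As a list the striated muscle miRNAs were not called (median -0.70, 0.02 with total counts, camera adjusted p = 0.185). With the pair term the list was lower in indigenous breeds (camera adjusted p = 0.0127), a call lost with an estimated correlation (adjusted p = 0.944), and its median was 0.00 in the first pair and -0.68 in the second. The 0.00 is the value of miR-499-3p, which had 0 reads in both libraries of the first pair, and is not a measured lack of change. Without Landrace the median of the striated muscle list was -1.51, and without Diannan Small Ear it was 0.62. These fits are unbalanced over the library pairs.

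The miRNAs inside slow-fibre myosin genes, miR-208b, miR-499-5p and miR-499-3p, all had lower estimates in indigenous breeds, and 0 of 3 passed. All 3 are also members of the striated muscle list, so those list tests are not independent. miR-208b was 2.25-fold lower in Diannan Small Ear than in Landrace (2.02 to 2.50) and miR-499-5p 2.06-fold (1.76 to 2.42), or 3.73-fold and 3.43-fold with total counts, while miR-499-3p had 0 reads in both. In Tibetan against Yorkshire they were 1.60-fold (1.27 to 2.0) and 1.61-fold lower (1.48 to 1.74), but 1.79-fold and 1.78-fold higher with total counts. The list was not called (median -0.86, camera adjusted p = 0.118). The pair term gave an adjusted p of 0.0117, lost with an estimated correlation (adjusted p = 0.944), and with total counts 2 of the 3 edgeR estimates were higher, while the list median was -0.47 (camera adjusted p = 0.0803). Leaving out 1 library moved the median from -2.45 (without Tibetan) to 0.62 (without Diannan Small Ear).

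Among 22 tested miRNAs of adipocyte differentiation and lipid metabolism, 14 had higher and 8 lower estimates in indigenous breeds, and 0 passed. miR-143-3p measured 12658 ± 2686 against 10210.0 ± 3966 CPM (log2 fold change 0.31 ± 1.14), miR-27b-3p, an inhibitor of adipocyte differentiation, -0.18 ± 1.19, and miR-21 -0.42 ± 1.83. The list median was 0.24 (camera adjusted p = 0.738), and ranged from 0.01 (without Diannan Small Ear) to 0.42 (without Landrace) with 1 library left out. The median of all miRNAs was 0.13 on the same measure. By edgeR log2 fold change it was 0.12 with TMM and -0.02 with RLE scaling. For muscle growth, regeneration and atrophy, 19 of 35 members had higher and 16 lower estimates, with miR-486 and miR-26a (0.11 ± 1.29) among the higher and miR-27b-3p among the lower. That list's median was 0.01, its mean -0.12 and the direction of its test was down (camera adjusted p = 0.118), and leaving out 1 library moved the median from -0.28 (without Yorkshire) to 0.04 (without Landrace).

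The imprinted DLK1-DIO3 cluster, a group of miRNAs expressed from the maternal chromosome, was the 1 list of 14 called between the types. It was higher in indigenous breeds, with a median of 0.97 and a camera adjusted p of 4.14e-05. The call was lost with an estimated correlation (adjusted p = 0.577), a setting at which no list was called. Of 9 tested members 8 had higher estimates and 0 passed alone, and with total counts 6 were higher, at a list median of 1.34 that was still called (camera adjusted p = 0.00209). The median of all miRNAs moved as well, from 0.13 to 0.46, so the excess of the list was 0.84 and 0.87, or 0.82 and 0.59 on log2(CPM + 1). miR-758 measured 10.8 ± 8.25 against 4.25 ± 1.67 CPM (log2 fold change 1.36 ± 1.01), miR-369 27.8 ± 27.8 against 11.1 ± 7.31 CPM and miR-127 937 ± 1197 against 832 ± 1146 CPM (0.17 ± 2.22). In the library pairs the median was 0.16 between Diannan Small Ear and Landrace and 1.57 between Tibetan and Yorkshire, the 85.6th and 99.8th percentile of 10000 random lists matched on expression. In Yorkshire every tested member but miR-127 and miR-369 had 10 or fewer reads. Without that library the median was 0.47 and the list was no longer called.

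**Figure D3:**
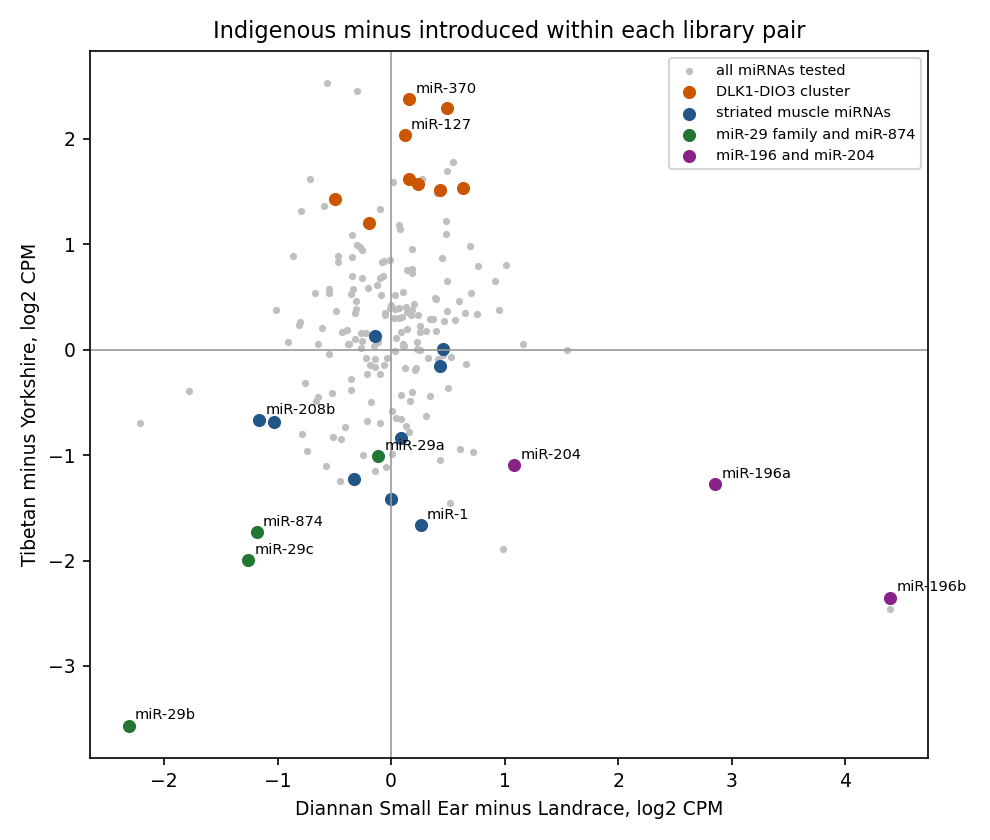
Difference of indigenous minus introduced library within each library pair, in log2 CPM, for the 197 tested miRNAs (horizontal axis, Diannan Small Ear minus Landrace, vertical axis, Tibetan minus Yorkshire). DLK1-DIO3 members (median 0.16 and 1.57) lie above 0 on the vertical axis, and miR-29b, miR-29c and miR-874 are below 0 on both.

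The let-7 family, whose members favour differentiation, had lower estimates in indigenous breeds for 9 of 9 members under TMM, RLE and total-count scaling, and 0 passed (let-7a -0.35 ± 1.67, let-7f -0.18 ± 1.43, let-7g -0.12 ± 0.87). Its median was -0.11 (camera adjusted p = 0.491), and 0.27 with total counts. Within the library pairs it was -0.27 in the first and 0.03 in the second, and 4 of the 9 were lower in both. Leaving out 1 library turned it, to 1.03 without Tibetan and 1.21 without Landrace, against -1.48 without Yorkshire and -1.27 without Diannan Small Ear. These fits are unbalanced over the library pairs. The let-7 median was 2.19 for Diannan Small Ear minus Tibetan and 2.42 for Landrace minus Yorkshire. In the miR-30 family 7 of 10 estimates were higher with TMM and 2 with RLE scaling, with miR-30a-5p at 0.12 ± 1.01, miR-30d at 0.13 ± 1.07 and miR-30e-5p at 0.10 ± 0.91. Its median was 0.14, its mean -0.00 and its test direction down (camera adjusted p = 0.738), and the median ranged from -0.56 (without Yorkshire) to 0.45 (without Landrace) with 1 library left out. The proliferation-linked miR-17-92 and paralogous clusters had 7 of 8 higher estimates (median 0.23, camera adjusted p = 0.715), with miR-92a at 0.26 ± 0.82, miR-20a at 0.23 ± 2.10 and miR-19b at 0.50 ± 1.41, and the median ranged from -0.68 (without Tibetan) to 1.41 (without Diannan Small Ear). HOX-cluster miRNAs had 3 of 5 higher estimates (median 0.79, camera adjusted p = 0.447), with miR-10b at 1.14 ± 2.92, miR-10a-5p at 0.20 ± 2.30 and miR-196b at -0.66 ± 1.92. Total-count scaling called the HOX list higher (camera adjusted p = 0.0180). The HOX median was 1.95 without Tibetan and -0.48 without Diannan Small Ear, in fits that are unbalanced over the library pairs.

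With all 4 libraries, none of the lists of markers of other cell types that a muscle sample could hold was called between the types. Erythroid markers had a median of 0.25 with a test direction of down (camera adjusted p = 0.968), and miR-451 measured 149 ± 120 against 102 ± 12.2 CPM, while miR-16 had -0.19 ± 0.89. White blood cell markers had 7 of 7 higher estimates with TMM and 5 with total counts (median 0.28, camera adjusted p = 0.447), among them miR-146a-5p (0.37 ± 0.86), miR-150 (0.28 ± 0.90) and miR-142-5p (0.18 ± 0.90). Endothelial markers had a median of 0.24, also with a test direction of down (camera adjusted p = 0.951), with miR-126-5p at 0.09 ± 0.96, miR-126-3p at 0.78 ± 1.34 and miR-424-5p at 0.20 ± 1.35. With 1 library left out the erythroid median ranged from -0.28 (without Yorkshire) to 0.30 (without Landrace) and the endothelial median from -0.50 to 0.06, in the same fits.

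Stromal markers, led by miR-143-3p, miR-21 and miR-199a-3p (0.28 ± 1.03), had 9 of 10 higher estimates and a median of 0.20 (camera adjusted p = 0.715). Without Diannan Small Ear the stromal median was 1.28, and without Tibetan it was -0.78, in fits that are unbalanced over the library pairs. The stromal median was -2.32 for Diannan Small Ear minus Tibetan and -1.74 for Landrace minus Yorkshire. Liver markers had 2 of 4 higher estimates and a median of -0.16 (camera adjusted p = 0.196), with miR-192 at 0.25 ± 2.40, miR-885-5p at -0.21 ± 1.12 and miR-194a at 0.19 ± 0.85. Without Diannan Small Ear the liver median was -1.55, and without Tibetan it was 0.09, again in unbalanced fits. Epithelial markers (miR-182 -0.37 ± 1.84, miR-183 -0.43 ± 1.32) and the neural marker miR-7 (-0.47 ± 1.30) had too few tested members for a list test. Between the library pairs the liver markers moved together only in part. miR-192 had 2989 reads in Diannan Small Ear and 2314 in Landrace against 25 in Tibetan and 13 in Yorkshire, and miR-122 had 16 and 78 against 10 and 9. With TMM scaling the log2 difference of miR-192 was 6.05 for Diannan Small Ear minus Tibetan and 5.79 for Landrace minus Yorkshire. That of miR-122 was -0.07 and 1.44, so it was higher only in Landrace.

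The authors' deposited table gives an FDR under 0.05 for 83 miRNAs, 39 higher and 44 lower in indigenous breeds. In 82 of the 83 the larger difference between libraries of a type exceeded the difference between the types on the log2(CPM + 1) scale. That comparison sets the larger of 2 differences between single libraries against a difference of means, and its share over all miRNAs was not computed. By the deposited CPM, types did not overlap in 1 of the 83, miR-29b, for which the authors' deposited table gives a fold of 0.141 and an FDR of 0.0162. With total counts, types did not overlap in only 4 of all 197 tested miRNAs (2.03%). The first count therefore cannot show whether the 83 differ from the other miRNAs, and the second does not set them apart.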

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

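The alternatives with a term for the library pair, and all settings of the comparisons within library pairs, were chosen after seeing the data. The count of 0 miRNAs between the types held in every alternative set before the data were examined, with 0 to 7 at an unadjusted p under 0.05. With the library-pair term the count was 1 with edgeR, 1 with RLE scaling and 1 with limma-voom, miR-29b each time, and 0 with DESeq2, total counts, no filter or the strict filter, which leaves miR-29b out. The cause was not tested.

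The counts of at least 2-fold differences within types stayed within 1.5 times in all alternatives. Between Diannan Small Ear and Landrace the count was 17, and 64 with total counts (4 higher, 60 lower in place of 8 and 9; RLE 6 and 12). Between Tibetan and Yorkshire it was 47, 155 with total counts (153 higher, 2 lower in place of 28 and 19; RLE 23 and 25) and 27 with at least 50 counts in 1 library, where fewer miRNAs entered. Non-overlapping types numbered 4 with total counts. The mean share of miR-10b was 28.4% with miR-1, the most abundant miRNA, left out of the totals. Total counts shift every ratio of 2 libraries by 1 constant factor, and why the scalings differ was not tested.

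The lists called numbered 1, against 0 with an estimated correlation, 2 with total counts, 0 with the strict filter (which leaves the DLK1-DIO3 list too few members), 3 with the pair term and 0 with the pair term and an estimated correlation. With 1 library left out they ranged from 0 to 4. The DLK1-DIO3 median stayed at 0.97 with an estimated correlation, without and with the pair term, and was not called (adjusted p = 0.577 and 0.944). With an estimated correlation camera rests on 2 residual degrees of freedom, or 1 with the pair term. A call lost there therefore cannot show that the members of a list move together. It ranged from 0.47 to 1.56 with 1 library left out, where a lone library is assumed to vary like the other type and the library pairs are not balanced.

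Of 48 named miRNAs 0 passed in any fit set before the data were examined. The sign changed for 4 with RLE, 15 with total counts, 4 with DESeq2, 4 with limma-voom and 3 with the pair term, and 38 differed in sign among the fits with 1 library left out. The labels give no replicate numbers, so the library pairs come from the values and not from the design. Rows sharing a name could not be treated in another way, since every name was unique. Thinning all libraries to the smallest total left r at 0.775 or less within types, and leaving out the 10 most abundant miRNAs of each library at 0.711 or less.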

Other observations

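The library-pair comparisons, the test of the arm ratios, of exchanged labels, of the authors' means, of the estimated correlation and of the miR-29b share were chosen only after the result was seen. miR-196a and the rows miR-196b and miR-196b-5p, all from HOX clusters, and miR-204 differed at least 2-fold in both library pairs but in opposite directions with TMM scaling. miR-196b had 125 reads in Diannan Small Ear and 3 in Landrace, 38.5-fold higher (95% counting interval 12.9 to 189), against 31 in Tibetan and 86 in Yorkshire, 5.33-fold lower (3.50 to 8.31). miR-196a was 7.92-fold higher in the first pair (5.13 to 12.8) and 2.53-fold lower in the second (1.40 to 4.62). miR-204 was 2.12-fold higher (1.94 to 2.32) and 2.20-fold lower (1.36 to 3.56). With total counts miR-196b, miR-196a and miR-204 were 23.2-fold, 4.77-fold and 1.28-fold higher in the first pair. In the second miR-196a and miR-204 were 1.13-fold and 1.30-fold higher in Tibetan, so the opposite direction was left for miR-196b (1.86-fold lower) and miR-196b-5p (2.02-fold lower). These ratios were not tested between breeds, which had 1 library each.

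The liver-specific miR-122 had 16 reads in Diannan Small Ear and 78 in Landrace, 5.27-fold lower (3.05 to 9.67), or 8.75-fold with total counts. Its 10 and 9 reads in Tibetan and Yorkshire gave a log2 difference of -0.70 with TMM scaling, but a level 1.65-fold higher in Tibetan with total counts. Between Tibetan and Yorkshire, miR-127 was 4.17-fold higher in Tibetan (2.99 to 5.94), miR-500 3.10-fold (1.92 to 5.25), the erythroid miR-144 3.09-fold (2.44 to 3.96), miR-369 2.92-fold (1.97 to 4.46) and miR-362 2.82-fold (2.34 to 3.43). miR-885-5p was 3.76-fold lower (2.82 to 5.06), miR-1 3.18-fold (3.17 to 3.18), miR-15a 2.76-fold (2.20 to 3.46) and miR-340 2.38-fold (2.17 to 2.61). miR-29a, the third member of the miR-29 family, was 2.02-fold lower in Tibetan (1.88 to 2.17), and 717 and 719 reads in Diannan Small Ear and Landrace gave a log2 ratio of -0.12 (-0.27 to 0.03). With total counts miR-29a was 1.80-fold lower in Diannan Small Ear than in Landrace. Total counts make every ratio of Tibetan over Yorkshire 2.86 times larger, so that miR-15a (1.04-fold), miR-340 (1.20-fold) and miR-29a (1.42-fold) turned higher in Tibetan, and miR-885-5p and miR-1 were 1.32-fold and 1.11-fold lower.

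The libraries paired across the types, and the split of Diannan Small Ear and Landrace against the rest gave 109 calls, where the types and the remaining split gave 0 each. With 3 splits no share under 0.05 can be reached, and the 109 calls restate the structure of the libraries that the correlations show. More or less transcription of the precursors is argued against as the whole cause, since the ratio of the 2 arms of 19 precursors changed by a median of 2.20 on the log2 scale between breeds of a type, against 0.33 within library pairs, in the same direction in both types for 18 of them, such as miR-374a, miR-28 and miR-126. Separate quantification of the library pairs fits, since all 542 of the authors' means follow the rule by these pairs and 518 follow it with the other crossing. Of the 542, 505 equal the plain mean of both libraries, so only the remaining means bear on the rule. A batch of library preparation or counting may therefore underlie the pairing, while breed, age or sex of the animals stays open and untested. Labels exchanged between the types (Tibetan with Landrace, or Diannan Small Ear with Yorkshire) cannot be told apart from this, since both predict what was seen, that 4 of 4 libraries correlate best with a library of the other type.

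The DLK1-DIO3 list was called higher in indigenous breeds at a median of 0.97. Dependence on a single library fits, since the adjusted p by camera was 0.524 without Yorkshire, where miR-127 had 40 reads against 320 in Tibetan. Members of a cluster moving together, so that the preset correlation is too small, stays open. At the estimated correlation the adjusted p by camera was 0.577, but that setting rests on 2 residual degrees of freedom and no list was called. The lost call therefore cannot decide whether the members move together. A difference in imprinted expression between the types therefore remains a hypothesis that may rest on the Yorkshire library.

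miR-29b was lower in the indigenous library of both pairs. Counting noise is argued against, since the highest upper bound of the 95% interval of the log2 ratio was -1.52. Reads of miR-29c counted as miR-29b, at 1 rate per library pair, are argued against as far as counting error goes, since miR-29b was 3.64% of the reads of both in Diannan Small Ear against 9.64% in Landrace (Fisher's exact p = 0.0155) and 13.0% in Tibetan against 33.9% in Yorkshire (Fisher's exact p = 0.000959), tests that compare libraries, not breeds, and treat reads as independent molecules, with 6 reads behind the first. A lower miR-29b level in indigenous breeds may be a biological difference, as a hypothesis, although the call needs the pair term and 13 fits set before the data were examined gave log2 fold changes of -4.34 to -2.09 with adjusted p of 0.990 to 1.00. Age, sex and pooling of the animals stay open and untested.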
